A study of Mus musculus with 4 samples.

How the data were processed

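Single-cell RNA was measured in 4 droplet libraries (10x Genomics) of mouse pancreatic ductal adenocarcinoma, 1 library per group. Per the submitters' protocol, each library pooled tumour pieces from 3 animals, dissociated with enzymes. The groups were taken from the labels: control (PBS), PH (paricalcitol and hydroxychloroquine), G (gemcitabine) and GPH (all 3 drugs). The treatment label of GPH breaks off after gemcitabine at 60 mg per kg, so its group came from the sample title. No replicates exist, so no test was run and no p-value is given.

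The deposited matrices hold raw UMI counts per gene and barcode, with 32285 features per library and no normalization. Per the submitters' processing notes, the counts were made with Cell Ranger 6.1 against mm10, while the file headers name Cell Ranger 7.0.1. The lowest total among the deposited barcodes was 500 UMIs in each library, and how barcodes were called is not stated. Gene positions are those of GENCODE vM21 on mm10, matched by Ensembl ID for all 266 genes looked up. Where features share a symbol, only the first was counted. This holds for Ddit3, with the overlapping entries ENSMUSG00000116429 and ENSMUSG00000025408 on chromosome 10.

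Cells were kept with at least 500 UMIs, at least 300 detected genes and at most 20% mitochondrial UMIs. Scrublet, run per library in scanpy 1.11.5, was used to remove doublets. Its automatic threshold called 1, 0, 1198 and 3 doublets in control, PH, G and GPH. After this was seen, the highest scores were removed in every library at a rate of 0.8% per 1000 cells, which took out 977, 2056, 1573 and 168 barcodes. The cells kept numbered 10074 in control, 13977 in PH, 12449 in G and 4411 in GPH. The 4 libraries were clustered together without batch correction, from 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9, scikit-learn 1.9.0). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 were used.

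Cell classes came from markers of 17 cell types, listed before the data were examined, as were the gene lists, the comparisons, the alternatives and the rule for named genes. A cluster could take a type's name when at least 3 markers reached 50 CPM and at least a 2-fold excess over the other cells, and its leading genes did not speak against it. Vimentin-high clusters 0, 1, 2, 3, 4 and 6 met this for no type. Cluster 7 held fibroblast markers (Col1a1, Col3a1, Col5a1, Dcn and Dpt) but was left unnamed, because it had Cdkn2a and almost no Xist, unlike fibroblast-like cluster 8. Broad populations were therefore set after the clusters had been seen. Immune clusters had Ptprc, the gene of the leukocyte antigen CD45, at 50 CPM or more. Of the others, keratin-high clusters had Krt19 at 1000 CPM or more, and vimentin-high clusters had Vim at 2000 CPM or more and a median depth of at least 1/3 of their libraries' medians. Both had Xist under 50 CPM. Clusters 22 and 23 also passed the marker count for ductal tumour but were left unnamed. They held 1 and 0 cells of control and 5 and 13 cells of PH, too few for a contrast. The planned ductal tumour class, taken as cluster 24 alone, had no cell in control or PH. Contrasts against control were therefore made in vimentin-high cells, and the ductal tumour-like cluster 24 served for GPH against G. Macrophages and T cells were compared for PH and G against control, because GPH held too few of them, and clusters 7 and 22 were added after the data had been seen.

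Within a population with at least 100 cells in both libraries, UMIs were summed per library and scaled to the population's total (CPM). Ratios carry exact conditional binomial 95% intervals and shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and say nothing about the spread between animals. A count of 0 was given the upper limit of 3 counts. A gene counted as measured at 20 CPM and 20 UMIs over both libraries. For 33 gene lists, the median log2 ratio over measured members (at least 5) is given with an exact order-statistic 95% interval and with its percentile among 10000 random lists matched on expression in 20 bins. The percentile describes these libraries and is not a test. Members at 1.5-fold or more are counted by size alone.

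Named genes had at least 50 CPM in 1 of the 2 libraries and were ranked by the interval bound of the log2 ratio nearest to 0. The 10 highest and 10 lowest were taken, or 5 and 5 for macrophages and T cells, and a few of them are not printed. Left out were mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, sex-linked and predicted genes. Genes at under 1/10 of their CPM in another class of at least 100 cells of that library were left out too, since free RNA could carry them. List members with the largest ratios, and those a list is named for, are also given. The intervals and list medians were tested on simulated data in which 200 genes were changed 2-fold or 4-fold and the autophagy list was shifted by 0.5 log2. In 4 simulated comparisons, 95.0 to 95.8% of true ratios lay inside their intervals, and the shifted list's median came out at 0.49 to 0.53. The simulated counts held only Poisson counting error, which the intervals assume, and no spread between cells or animals. This coverage thus checks the computation and does not show that the intervals hold for real cells. An unshifted list took percentiles as low as 2.85 in the simulations, so a low percentile alone arises without any difference.

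The alternatives were a 10% mitochondrial limit, at least 1000 UMIs and 500 genes, doublets kept, Leiden resolution 2.0, each cell assigned by its own markers, and shares over the cells outside the keratin-high population. For ratios they were scaling by the median of ratios, the mean of each cell's CPM, cells thinned to 1000 UMIs, members at 100 or at 5 CPM, cells without a UMI of the mitosis list, and classes at equal weight. After the data had been seen, cluster 7 alone, clusters 0, 1, 2, 6 and 7 at equal weight, and lists without the genes that follow the library pairs were added. The equal weights ignored the minimum of 100 cells: clusters 0, 1 and 2 held 77, 60 and 79 cells in GPH.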

Results

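The RNA of single cells was sequenced from mouse pancreatic ductal adenocarcinoma, with 1 library for each of 4 groups: control (PBS), PH, G and GPH. PH stands for paricalcitol, which activates the vitamin D receptor, and hydroxychloroquine, which raises the pH of lysosomes and so blocks the last step of autophagy. G stands for gemcitabine, a nucleoside analogue that stops DNA synthesis, and GPH for all 3 drugs. Each library pooled tissue from 3 animals, and there were no replicates. The deposited counts came to 158887422 UMIs in control, 190110092 in PH, 144152432 in G and 143298547 in GPH, over 13120, 18589, 16748 and 7918 barcodes. More than 20% of the UMIs were mitochondrial in 15.6% of the barcodes of control, 12.7% in PH, 15.6% in G and 41.0% in GPH. After filtering, 10074, 13977, 12449 and 4411 cells were kept, with median depths of 9636, 7830, 4607 and 20015 UMIs.

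The libraries differed in which cells they held. Vimentin-high cells, with the mesenchymal filament gene Vim and the cell cycle inhibitor gene Cdkn2a, made up 80.0% of kept cells in control, 76.5% in PH, 15.4% in G and 33.8% in GPH. Keratin-high cells, with the ductal keratin gene Krt19, made up 10.5% of G (95% interval 9.97 to 11.1) and 48.0% of GPH (46.5 to 49.5), against 1 cell in control and 5 cells in PH. With each cell assigned by its own markers, the ductal tumour type took 4.50% of control, 8.41% of PH, 9.65% of G and 46.7% of GPH. That setting types every cell and has no Krt19 threshold. Among the keratin-high clusters, the ductal tumour-like cluster 24 held 2.66% of G and 22.6% of GPH. In control it held 0 of 10074 cells, which allows a share of up to 0.0298%, and in PH 0 of 13977 cells, which allows up to 0.0215%. Immune cells made up 71.4% of G (70.6 to 72.2), 12.95% of control (12.3 to 13.6), 7.70% of PH (7.26 to 8.15) and 4.60% of GPH (4.003 to 5.26). By each cell's own markers these shares were 70.3%, 38.2%, 35.5% and 15.4%. That setting gives every cell a type, so vimentin-high cells, which no marker list describes, can count as immune in it. Outside the keratin-high cells, immune cells were 79.8% of G and 8.85% of GPH. Each population's median depth differed between libraries, from 9374 UMIs in PH to 14862 in GPH for vimentin-high cells and from 2414 in GPH to 3527 in G for immune cells.

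**Figure D1:**
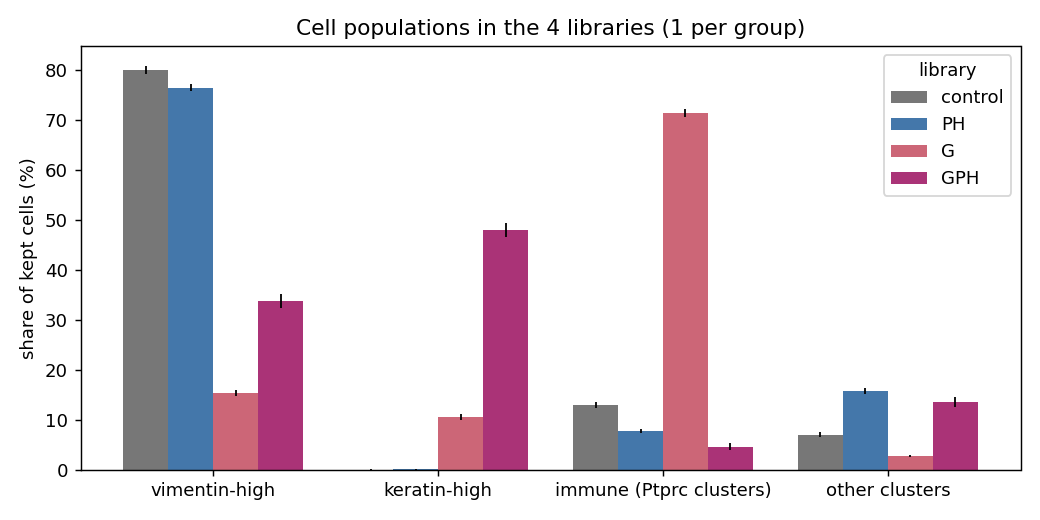
Share of kept cells, in percent, in each of 4 populations, with 1 bar per library and exact 95% intervals for counting error. Vimentin-high cells led in control (80.0%) and PH (76.5%), immune cells in G (71.4%) and keratin-high cells in GPH (48.0%).

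Among immune cells, T cell-like clusters 13, 14 and 18 held 31.5% of all kept cells in G, 4.39% in control, 3.26% in PH and 1.20% in GPH. Macrophage or monocyte-like cluster 10 held 14.3% of G, 2.54% of control, 2.50% of PH and 1.16% of GPH. NK cell-like cluster 12 held 8.68%, 2.58%, 0.758% and 0.317% in the same order. Neutrophil-like cluster 9 was 6.73% of G and 0.298% of control, and dendritic-like cluster 16, which also held macrophage markers, was 6.72% of G and 0.139% of control. As a share of immune cells, the neutrophil-like cells were 9.43% in G and 2.30% in control, the dendritic-like cells 9.42% and 1.07%, and the NK cell-like cells 12.2% and 19.9%. Plasma cell-like cells were 1.53% of G and 0.218% of control. In GPH they were 0 of 4411 cells, which allows a share of up to 0.0680%. Fibroblast-like cluster 8 stayed under 1% in every library, at 0.685% in control, 0.272% in PH, 0.201% in G and 0.771% in GPH. Cells outside the 3 main populations were 6.99% of control, 15.8% of PH, 2.72% of G and 13.6% of GPH, and those of PH were mostly in cluster 19, with 13.2% of that library. Clusters 19, 5 and 11 met the Vim and Xist limits of vimentin-high cells, with Vim at 2314, 2941 and 2807 CPM. They missed only the depth limit of 1/3, at 0.260, 0.297 and 0.273 of their libraries' medians. The vimentin-high shares thus depend on that limit.

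Transcripts that set the libraries apart were also found in vimentin-high and keratin-high cells. The Y-linked genes Kdm5d, Uty and Eif2s3y together reached 8.43 CPM in vimentin-high cells of G (7.39 to 9.59) and 11.95 CPM in those of GPH (10.7 to 13.3), against 0.0672 in control and 0.463 in PH. In cluster 7 they reached 18.4 CPM in G and 13.5 CPM in GPH, against 0 UMIs in control and 0.241 CPM in PH. Contrasts within cluster 7 alone therefore cross this difference too where they set G or GPH against control or PH. In keratin-high cells they reached 32.9 CPM in G and 37.8 CPM in GPH. Immune cells held 0.394 CPM in G and 0 UMIs in GPH, while their Xist, made from the inactive X chromosome, was 1034 CPM in G and 1753 CPM in GPH. In addition, 6 genes set control and GPH apart from PH and G by at least 1.5-fold in all 10 ratios that vimentin-high, macrophage, T and NK cells allowed, with GPH in the first of these alone. Among them, Dync1i2, Hypk, Ap2b1, Nmt1 and AY036118 were higher in control and GPH. In vimentin-high cells Nmt1, which attaches myristate to proteins, was at 113, 25.9, 26.6 and 101 CPM in control, PH, G and GPH. The other ways of pairing the 4 libraries gave 0 such genes each. In vimentin-high cells alone, 42 of 2049 genes followed this split, and 18 and 13 genes followed the other pairings. Of the contrasts below, GPH against control alone does not cross this split, but it crosses the Y-linked difference, as do G against control and GPH against PH.

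**Figure D2:**
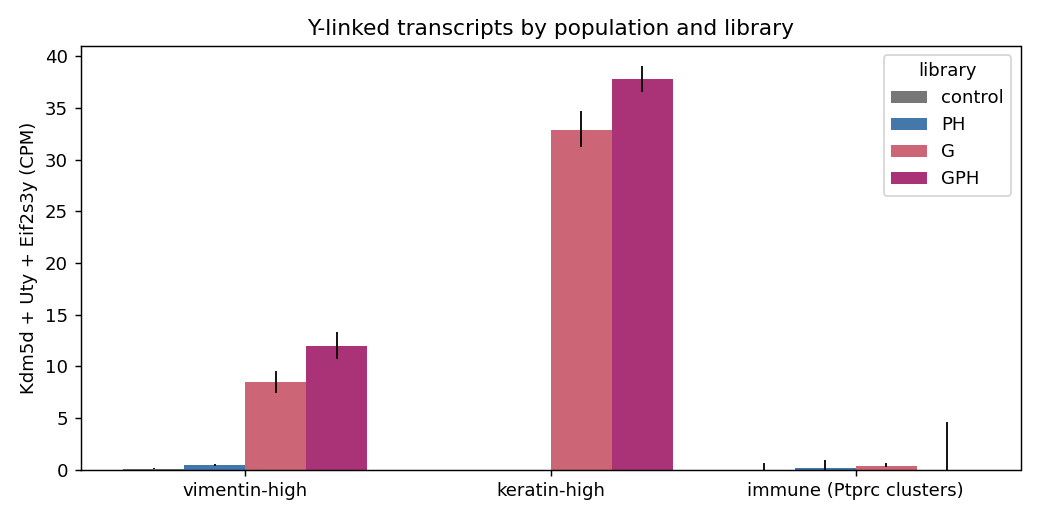
Summed level of the Y-linked genes Kdm5d, Uty and Eif2s3y, in CPM, by population and library, with 95% counting intervals; the 1 and 5 keratin-high cells of control and PH are not drawn. Bars for G (8.43) and GPH (11.95) stand above control (0.0672) in vimentin-high cells.

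PH against control asked what paricalcitol and hydroxychloroquine did without chemotherapy. In vimentin-high cells, genes of antigen presentation and interferon signalling were lower in PH, and Tnfaip3 and Slc7a11 were the highest named genes. All 6 measured genes of the MHC class II list were at least 1.5-fold lower (median log2 -1.58, interval -1.71 to -1.27, percentile 0). Among them, Cd74, the class II invariant chain, stood at 144 CPM against 471, and H2-Ab1 at 81.8 against 266. All 6 measured type I interferon genes were at least 1.5-fold lower too (median -1.03, interval -1.67 to -0.73), among them Isg15, a ubiquitin-like protein, at 16.5 against 52.7 CPM and the antiviral tether gene Bst2 at 122 against 336. The MHC class I list had a median of -0.63 with 4 of 6 members lower, yet B2m, its light chain, differed by 0.06 log2. Hypoxia and glycolysis genes had a median of -0.63 (interval -0.89 to -0.19), with 9 of 16 lower and none higher, including the aldolase gene Aldoa at 505 against 975 CPM and the hexokinase gene Hk2 at 229 against 424. In cluster 7 alone, which held 20.99% of control and 3.38% of PH cells, the hypoxia median was -0.90, but the interferon median was 0.00 and the MHC class II median -0.14. The class II and interferon differences of the whole population were thus not seen within that cluster.

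The genes named for vimentin-high cells of PH against control began with Tnfaip3 (ENSMUSG00000019850, mm10 chromosome 10, 19000910 to 19015657), a brake on NF-kappaB, at 63.2 against 11.01 CPM or 5.74-fold (5.41 to 6.09). Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), the cystine importer, was 5.65-fold higher (5.35 to 5.98), and the monocyte attractant Ccl2 was 3.09-fold higher, at 962 against 312 CPM. Also higher were the nuclear receptor gene Nr4a2 (3.67-fold), the long noncoding RNA Neat1 (3.06-fold), Idh1, which makes NADPH (2.95-fold), Lbp, the lipopolysaccharide-binding protein (2.94-fold), Hmga2 (2.36-fold), Klf4 (2.26-fold) and Nid1 (2.25-fold). Ccl2 and Slc7a11 were also leading genes of cluster 4, which held 2531 of 10694 vimentin-high cells in PH and 58 of 8064 in control. The lowest beside Cd74, H2-Ab1 and Isg15 were Nmt1 (4.38-fold lower), the smooth muscle actin gene Acta2 (3.87-fold), the Notch target Hes1 (3.74-fold, 110 against 413 CPM), the tubulin gene Tuba1c (3.17-fold), H2-Eb1 (3.11-fold), Sprr1a (3.05-fold) and Hypk (2.94-fold). Acta2 and Hes1 lead cluster 7, which held 2115 of 8064 vimentin-high cells in control and 472 of 10694 in PH. Within it Acta2 was 1.58-fold, Hes1 2.49-fold, Cd74 1.06-fold, H2-Ab1 1.13-fold, H2-Eb1 1.07-fold and Isg15 1.46-fold lower. Tnfaip3 was 7.20-fold, Slc7a11 5.65-fold, Idh1 1.83-fold and Lbp 1.79-fold higher there. Nmt1 and Hypk belong to the genes of the library pairs, and in vimentin-high cells Hes1 and Tuba1c followed the same split, with 632 and 150 CPM in GPH, as did Hk2.

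Of the lists closest to the 2 drugs, autophagy, lysosome and ER chaperone genes had medians near 0 in vimentin-high cells of PH against control. Autophagy genes had a median of -0.08 (-0.53 to 0.09), with 1 of 18 higher, 3 lower and 14 between. Rb1cc1, part of the kinase complex that starts autophagy, was at 34.6 against 22.8 CPM, while the ATG8-family genes Map1lc3a and Gabarap were at 100 against 176 and 529 against 862. Over 13 alternatives the autophagy median ran from -0.16 to 0.10, so no direction is given. Lysosome genes had a median of -0.09, with 1 of 16 higher, the proton pump gene Atp6v1a at 54.3 against 30.1 CPM, and 15 between. ER chaperones and ER-associated degradation genes had a median of -0.11, with 3 of 22 lower, and Hspa5, the ER chaperone BiP, at 470 against 567 CPM. The integrated stress response list had a median of -0.20, with 4 of 13 lower, including Ddit3, which encodes CHOP, at 24.02 against 45.2 CPM. Values of Ddit3 here and below count only the first of its overlapping entries. Over 13 alternatives it ran from -0.70, over members at 100 CPM or more, to -0.023 in cluster 7 alone. For the vitamin D receptor, Vdr was at 1.60 CPM in PH and 3.01 in control, and Spp1, a vitamin D target that encodes osteopontin, at 1539.7 and 1424. Cyp24a1, the most responsive vitamin D target in many tissues, had 2 of 129652959 UMIs in PH and 0 of 119077259 in control. It was thus almost absent from both libraries, and no response of it was seen.

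Macrophages of PH expressed more inflammatory cytokine genes than those of control. In the macrophage or monocyte-like class, 10 of 12 measured genes of the inflammatory macrophage list were at least 1.5-fold higher and none was lower, with a median of 2.47 (percentile 100). Il1a and Il1b, both interleukin 1 genes, were at 487 against 16.4 and 2566 against 372 CPM. Tnf was at 367 against 44.6 CPM and Ptgs2, the inducible cyclooxygenase, at 789 against 92.7. The neutrophil chemokine list had a median of 1.98, with 7 of 9 higher. Interferon genes went the other way (median -0.77, 7 of 13 lower). By the naming rule, Marco, a scavenger receptor (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), was at 192 CPM against 0 UMIs, at least 129-fold higher. Cxcl1, a neutrophil attractant, was 105-fold higher (67.3 to 175), Saa3, an acute-phase protein, 64.4-fold higher and Prg4, by the same limit, at least 38.0-fold higher. Il6 was at 115 CPM against 1 UMI, a ratio of 233 with an interval from 41.5 to 9211. The lowest were the lysozyme gene Lyz1 (21.7-fold lower), Ccdc163 (10.1-fold), the monocyte attractant Ccl8 (6.47-fold, 262 against 1692 CPM), Rhov (6.45-fold) and Yae1d1 (5.92-fold). T cells of the same PH library held 0 UMIs of Marco and 0.768 CPM of Cxcl1, while its 38 fibroblast-like cells held 799 CPM of Cxcl1, 1849 of Saa3, 216 of Prg4 and 138 of Il6. The class held 350 cells in PH and 256 in control.

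In the T cell-like class of PH against control, histone genes were the highest named genes. Hist1h2ap was at 2283 against 770 CPM (2.96-fold), Hist1h3f 3.20-fold, Hist1h3c 2.99-fold and Hist1h2ae 2.43-fold higher. Xcl1, a chemokine that attracts dendritic cells, was 4.92-fold lower, Cd40lg, the helper T cell ligand of CD40, 4.86-fold lower, Nmt1 4.11-fold, Arf6 2.40-fold and the antiproliferative gene Btg1 2.26-fold lower. Nmt1 belongs to the genes of the library pairs, and Btg1 followed that split in vimentin-high cells. T cells of G, on the same side of that split as PH, also had more Hist1h2ap than control (2774 CPM) and less Cd40lg and Btg1. Cytotoxic effector genes had a median of 0.13, with 10 of 11 between, and MHC class I genes -0.47, with 2 of 12 lower. In NK cell-like cells all 14 measured mitosis genes were at least 1.5-fold lower in PH (median -1.47), and 8 of 10 cholesterol genes were lower (median -1.46), from 106 cells in PH and 260 in control.

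G against control asked what gemcitabine alone did. In vimentin-high cells of G, 10 of 19 mitosis genes were higher over the whole population, which held a larger share of mitotic cells. Most members of the ER, hypoxia and cholesterol lists stood between 1.5-fold lower and higher. Of 19 measured mitosis genes 10 were at least 1.5-fold higher and none lower (median 0.62, interval 0.49 to 0.88, percentile 100). Cenpe and Cenpf, both kinetochore proteins, were at 61.1 against 25.9 and 145 against 71.2 CPM, and the proliferation marker Mki67 at 65.8 against 38.4. Mitotic cluster 6 held 435 of 1916 vimentin-high cells in G and 1209 of 8064 in control, and the mitosis median was -0.04 within it and 0.083 with 5 clusters at equal weight. The ER chaperones and ER-associated degradation list had a median of 0.25 (0.05 to 0.48, percentile 99.99), with 3 of 21 higher and none lower. Among its members, Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547) was at 936 against 567 CPM and Herpud1, which helps remove misfolded proteins, at 87.0 against 54.5. The integrated stress response list stood at -0.08, with Ddit3 at 45.2 CPM in both libraries. Autophagy genes had a median of -0.22, with 3 of 18 lower and none higher, including Bnip3, a mitophagy receptor induced by hypoxia, at 61.5 against 125 CPM, and lysosome genes a median of -0.14. Hypoxia genes had a median of -0.47 (7 of 17 lower), cholesterol genes -0.45 (4 of 11 lower), and dissociation and immediate early genes -0.54 (8 of 16 lower, 2 higher), among them Socs3 at 83.1 against 238 CPM. Interferon genes had a median of -0.44, but 0.14 in cluster 7 alone, so no direction is given.

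For DNA damage and the drug itself, the p53 target list had a median of -0.24 in vimentin-high cells of G against control, and 0.13 in cluster 7 alone. Within it Cdkn1a, which encodes p21, was at 60.5 against 33.8 CPM, while Phlda3 was at 28.0 against 70.9. Rrm1, a subunit of the ribonucleotide reductase that gemcitabine inhibits, was at 39.1 against 26.4 CPM, and Slc29a1, the nucleoside transporter ENT1, at 52.4 against 69.6. The named genes that were highest were Ptn, a heparin-binding growth factor (ENSMUSG00000029838, chromosome 6, 36714929 to 36810220; 4.92-fold, 4.72 to 5.13), the interferon-induced chemokine Cxcl10 (3.55-fold), complement C3 (3.23-fold), the hyaluronan synthase Has2 (3.08-fold), Arl6ip1 (2.50-fold), Cenpe and Col1a1 (each 2.36-fold) and the activin gene Inhba (2.30-fold). Ptn and Has2 lead cluster 7, which held 626 of 1916 vimentin-high cells in G, and within it they were 5.16-fold and 4.40-fold higher. In the same library Col1a1 reached 3294 CPM in fibroblast-like cells, against 91.5 in vimentin-high cells. The lowest were Nmt1 (4.26-fold lower), Hes1 (4.14-fold), Egln1, an oxygen-sensing hydroxylase (2.94-fold), Socs3 (2.86-fold), Ier2 (2.80-fold), Tuba1c (2.76-fold), Hypk (2.58-fold), Gadd45g (2.57-fold), Phlda3 (2.53-fold) and Hnrnpa0 (2.38-fold). All of these but Egln1 and Ier2 followed the split of the library pairs in vimentin-high cells, as did Mki67.

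The macrophages of G had more of the class II antigen presentation machinery than those of control. In the macrophage or monocyte-like class all 7 measured MHC class II genes were at least 1.5-fold higher, with a median of 3.17. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) was at 5506 against 443 CPM and Cd74 at 11588 against 2031, and Ciita, which switches these genes on, at 35.7 against 3.96. T cells of the same library held 31.2 CPM of H2-Aa. Saa3 was 117-fold and H2-Aa 12.4-fold higher. With control at its limit of 3 counts, Marco was at least 115-fold, Prg4 at least 44.2-fold and H2-M2 at least 41.3-fold higher. Marco, Saa3 and Prg4 were also among the highest named genes in macrophages of PH, at 192, 862 and 56.4 CPM. In these genes control thus differed from PH and G alike, which share a side of the library pairs. The 51 macrophage-like cells of GPH held 1172 CPM of Saa3. Fibroblast-like cells of G held 3149 CPM of Saa3. The lowest were the monocyte attractants Ccl12 (16.6-fold lower) and Ccl7 (13.6-fold), Pdpn, a membrane glycoprotein (13.4-fold), the neutrophil attractant Cxcl3 (13.4-fold) and Spp1 (9.34-fold, 357 against 3336 CPM). Inflammatory macrophage genes had a median of -0.49, with 5 of 11 lower and 3 higher, among which Cxcl9, a T cell attractant, differed by 1.43 log2. The alternatively activated list split, with 4 of 11 higher and 5 lower: Arg1, which breaks down arginine, was at 273 against 1064 CPM, and the lectin gene Mgl2 at 98.9 against 22.3.

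T cells of G had fewer cytotoxic transcripts than those of control, and more Foxp3 and Il2ra. In the T cell-like class 8 of 10 cytotoxic effector genes were at least 1.5-fold lower and none higher, with a median of -0.95. Gzma, granzyme A (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), was at 53.8 against 719 CPM or 13.4-fold lower, granzyme Gzmb at 234 against 870 and the chemokine Ccl5 at 3178 against 16108. NK cell-like cells of control, which sit beside T cells in the clustering, held 4897 CPM of Gzma. Of 8 regulatory T cell genes 4 were higher and none lower (median 0.78), including Foxp3, their lineage factor, at 29.9 against 8.34 CPM and Il2ra, the interleukin 2 receptor, at 74.7 against 20.5 (3.65-fold). Inhibitory receptors had a median of -0.30, with Lag3 at 61.2 against 189 CPM and Pdcd1, which encodes PD-1, differing by 0.10 log2. DNA replication genes had a median of 0.59, with 9 of 18 higher. The other named genes were Kcnq1ot1 (4.50-fold higher), the transcription factor Myb (4.47-fold), Hist1h2ap (3.60-fold) and Tent5a (3.52-fold), and on the lower side Ifitm1 (12.4-fold), Cd40lg (7.01-fold), Ccl5 (5.07-fold) and Btg1 (4.65-fold). Btg1 followed the split of the library pairs in vimentin-high cells. Hist1h2ap, Cd40lg and Btg1 were also named in T cells of PH, in the same directions. In these genes control thus differed from PH and G alike, which share a side of the library pairs. Ifitm1 was at 951 CPM in vimentin-high cells of control, against 173 CPM in its T cells. The class held 3916 cells in G and 442 in control, with 1683 and 272 of them in cluster 13, 1019 and 81 in cluster 14 and 1214 and 89 in cluster 18, led by Tnfrsf4, Ctla4 and Icos.

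GPH against control asked what all 3 drugs did together, and the series names autophagy and ER stress as what they were expected to raise. In vimentin-high cells, all 8 measured inflammatory fibroblast genes were higher in GPH and 10 of 11 cholesterol genes lower, while 8 of 18 lysosome genes were higher. Autophagy genes had a median of 0.35 (0.07 to 0.49, percentile 97.6), with 4 of 18 higher, 1 lower and 13 between. Sqstm1, the autophagy receptor p62 (ENSMUSG00000015837, chromosome 11, 50199366 to 50210827), was at 599 against 280 CPM (log2 1.10, 1.07 to 1.12), Vmp1 at 233 against 147 and Map1lc3b, which encodes LC3B, at 292 against 240. Bnip3 was at 36.9 against 125 CPM. The autophagy median was 0.02 in cluster 7 alone, which held 1128 of 1491 vimentin-high cells in GPH and 2115 of 8064 in control, and it ran from 0.02 to 0.39 over 13 alternatives. Lysosome genes had a median of 0.47 (0.25 to 0.86, percentile 99.8), with none lower. It was 0.40 in cluster 7 alone and ran from 0.28 to 0.73 over 13 alternatives. Lipa, the lysosomal acid lipase (ENSMUSG00000024781, chromosome 19, 34492318 to 34527474), was at 182 against 51.5 CPM, the protease gene Ctsb (ENSMUSG00000021939, chromosome 14, 63122462 to 63145923) at 384 against 126 and Ctsd at 207 against 128.

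For ER stress in vimentin-high cells of GPH against control, the ER chaperones and ER-associated degradation list had a median of 0.29 (-0.06 to 0.56, percentile 95.5), with 3 of 21 higher, 1 lower and 17 between. Dnajb9, a chaperone induced by the unfolded protein response (ENSMUSG00000014905, chromosome 12, 44205559 to 44210326), was at 84.3 against 32.1 CPM, Hspa5 at 836 against 567 and Xbp1, its transcription factor, at 77.3 against 52.7, while the translocon gene Sec61b was at 295 against 452. The ER list had a median of 0.26 in cluster 7 alone, and over 13 alternatives it ran from 0.03, over members at 100 CPM or more, to 0.39. The integrated stress response list had a median of 0.28 (-0.18 to 1.30), with 6 of 14 higher and 1 lower, and 0.48 in cluster 7 alone, and it ran from 0.21 to 0.89 over 13 alternatives. Dissociation and immediate early genes had a median of 0.70, with 9 of 16 higher and 1 lower, and 0.15 in cluster 7 alone, and 41.0% of GPH barcodes were over the mitochondrial limit, against 15.6% in control. The list's Ddit3 was at 126 against 45.2 CPM, the phosphatase subunit gene Ppp1r15a at 195 against 76.3, Atf3 at 518 against 211 and Atf4, the central factor of that response, at 237 against 134. Phgdh, the first enzyme of serine synthesis, was at 157 against 259.

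Cholesterol synthesis and uptake was the list furthest below control in vimentin-high cells of GPH, with 10 of 11 genes at least 1.5-fold lower and a median of -1.89 (-2.86 to -1.06), and -1.52 in cluster 7 alone. Idi1 (ENSMUSG00000058258, chromosome 13, 8885501 to 8892451) and Fdps (ENSMUSG00000059743, chromosome 3, 89093588 to 89101959), which make the isoprenoid precursors, were 9.13-fold (8.003 to 10.5) and 7.26-fold lower (6.80 to 7.76). In cluster 7 alone Idi1 was 8.47-fold and Fdps 3.02-fold lower. Fdps leads cluster 3, which held 818 cells in control and 6 in GPH. The named genes Cyp51 (3.98-fold lower), Hmgcs1 (3.91-fold) and Msmo1 (3.71-fold) belong to the same pathway. All 8 measured inflammatory fibroblast genes were at least 1.5-fold higher (median 1.63, and 1.19 in cluster 7 alone with 9 of 9 higher), including Ccl2 at 942 against 312 CPM and Il33, an alarmin, at 224 against 83.6. Collagens and matrix genes had a median of 0.75, with 8 of 13 higher, but 0.16 in cluster 7 alone. Of 9 oxidative stress genes 5 were higher (median 0.75), led by Hmox1, the haem oxygenase (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), at 608 against 103 CPM. Hmox1 leads cluster 7, where it was at 806 against 279 CPM and the list's median was 0.75, with 7 of 11 higher. MHC class I genes had a median of 0.58, with 3 of 7 higher. Mitosis genes had a median of -0.53, with 8 of 18 lower, but 0.23 with 5 clusters at equal weight, so no direction is given. Mitotic cluster 6 held 106 vimentin-high cells in GPH and 1209 in control.

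The highest named gene in vimentin-high cells of GPH against control was Lcn2, an iron-binding acute-phase protein (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), at 105 against 3.97 CPM, 26.5-fold higher (24.03 to 29.3). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) was 20.96-fold higher (19.1 to 23.01), the chemoattractant Rarres2 15.96-fold, C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136) 13.6-fold and the metalloprotease Mmp19 11.6-fold higher. Lbp (8.93-fold), the neutrophil attractant Cxcl2 (8.69-fold), Ptn (7.86-fold), complement C4b (7.85-fold) and the extracellular chaperone Clu (7.70-fold) followed. In cluster 7 alone Lcn2 was 16.02-fold, Cxcl2 14.9-fold, Saa3 10.4-fold, C3 7.05-fold and Ptn, which leads that cluster, 3.58-fold higher. Rarres2 was 9.03-fold, Mmp19 6.59-fold, Lbp 4.96-fold, C4b 4.50-fold and Clu 3.93-fold higher there. Other cells of GPH held more of some of them: Saa3 reached 7529 CPM and C3 5817 in fibroblast-like cells, Cxcl2 4211 in macrophages and Clu 2162 in keratin-high cells. Xist, at 1853 CPM in those fibroblast-like cells, was at 0.507 CPM in vimentin-high cells of GPH. Beside the cholesterol genes, the lowest were the fatty acid carrier Fabp5 (4.39-fold lower), the histone genes Hist1h2ae and Hist1h1b (each 4.21-fold) and Hist1h2ap (3.53-fold), and the actin-binding Tmsb10 (3.27-fold). Within cluster 7 Fabp5 was 2.96-fold, Tmsb10 2.76-fold, Hist1h2ae 2.18-fold, Hist1h1b 1.97-fold and Hist1h2ap 1.16-fold lower.

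**Figure D3:**
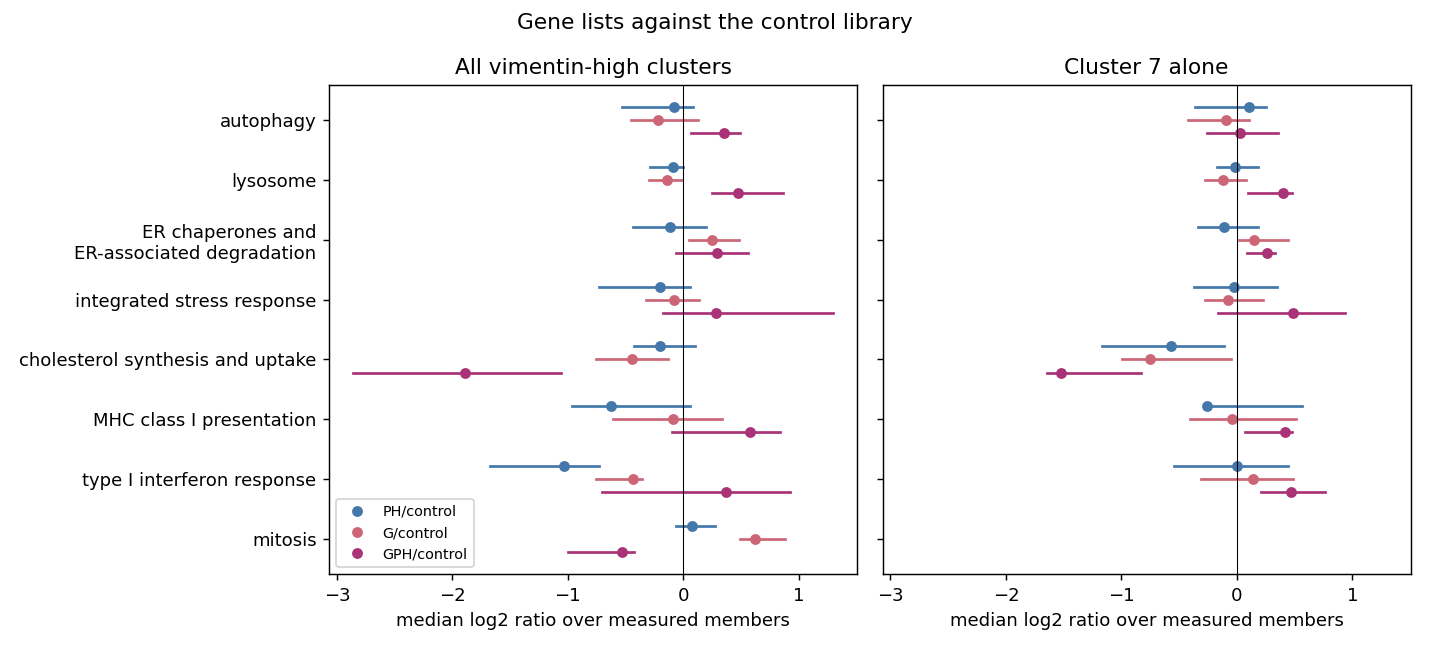
Median log2 ratio against control over the measured members of 8 gene lists, for PH, G and GPH, in all vimentin-high clusters (left) and in cluster 7 alone (right, where too few mitosis genes were measured); lines are exact 95% intervals of the median over genes. The autophagy median of GPH was 0.35 on the left and 0.02 in cluster 7, and the cholesterol median was -1.89 and -1.52.

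GPH against G asked what paricalcitol and hydroxychloroquine added to gemcitabine, and it could be made in keratin-high cells. In the ductal tumour-like cluster 24, 9 of 15 hypoxia genes, 6 of 11 MHC class I genes and 6 of 15 integrated stress response genes were at least 1.5-fold higher in GPH, and 22 of 23 ER chaperone genes stood between. The all-gene median log2 ratio was 0.22 there, and scaling by the median of ratios moved every ratio by 0.11. The integrated stress response list had a median of 0.47, with 1 lower; Ddit3 was at 52.5 against 14.9 CPM and Ppp1r15a at 98.9 against 47.0, while Cebpb was at 199 against 371. Dissociation and immediate early genes had a median of 0.90 there, with 9 of 16 higher. Autophagy genes had a median of 0.27, close to all genes (percentile 70.8), with 3 of 18 higher, among them Sqstm1 at 410 against 261 CPM. Lysosome genes had a median of 0.44 (percentile 99.2), with 4 of 24 higher, among them Ctsb at 394 against 228. ER chaperone genes had a median of 0.03 (percentile 7.28), with Hspa5 at 782 against 835 CPM and Os9, of ER-associated degradation, at 58.1 against 33.5; with scaling by the median of ratios the list stood at -0.08. MHC class I genes had a median of 0.60, with the nonclassical H2-T23 at 204 against 57.8 CPM and H2-D1 at 1528 against 832. Hypoxia genes had a median of 0.63, with Hk2 (ENSMUSG00000000628, chromosome 6, 82725025 to 82774454) at 292 against 144. In vimentin-high cells H2-T23 and Hk2 followed the split of the library pairs. The interferon list was split, with 6 of 12 higher and 2 lower; Ifit1 was at 15.0 against 88.2 CPM.

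The genes named in cluster 24 for GPH against G were, on the higher side, Ly6m (7.64-fold, 6.42 to 9.15), the immediate early gene Jun (6.18-fold, 557 against 90.2 CPM), mesothelin Msln (5.51-fold), AY036118 (5.10-fold), Hes1 (5.06-fold), and amphiregulin Areg, a ligand of the EGF receptor (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432; 4.92-fold). Ly6c1 (4.89-fold), Tuba1c (4.61-fold), Ido1, which breaks down tryptophan (4.50-fold, 201 against 44.6 CPM), and Txnip (3.98-fold) followed. The lowest were the kinase gene Sgk1 (6.46-fold lower, 5.74 to 7.27), Ifit1 (5.88-fold), Cxcl10 (4.30-fold), Bloc1s1 (3.68-fold), the trefoil mucosal peptide Tff2 (ENSMUSG00000024028, chromosome 17, 31141049 to 31144282; 3.48-fold, 1624 against 5654 CPM), Gstp1 (3.26-fold), the ductal factor Sox9 (2.72-fold), Erh (2.64-fold) and Insig1, a sensor of sterols (2.53-fold). AY036118, at 2817 CPM in immune cells of GPH, belongs to the genes of the library pairs, and Hes1, Tuba1c and Bloc1s1 followed that split in vimentin-high cells. In keratin-high cluster 22, Areg was 5.63-fold, Ido1 5.04-fold, Angptl4, a lipase inhibitor, 3.51-fold and Msln 3.45-fold higher, and Gpx2, a gut glutathione peroxidase, 17.02-fold and Tff2 6.98-fold lower. Cluster 24 held 331 cells of G at a median of 32906 UMIs and 999 of GPH at 46673.

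In vimentin-high cells of GPH against G, 13 of 21 lysosome genes and 7 of 14 integrated stress response genes were higher and 7 of 9 cholesterol genes lower. The lysosome list had a median of 0.77 (0.48 to 0.98), with none lower, but 0.40 in cluster 7 alone; Lipa was at 182 against 58.8 CPM and Ctsd at 207 against 99.0. Autophagy genes had a median of 0.40 (0.23 to 0.63), with 6 of 18 higher and 1 lower, and 0.18 with 5 clusters at equal weight; Gabarapl1 was at 68.2 against 33.4 CPM and Sqstm1 at 599 against 318. The integrated stress response list had a median of 0.75, which ran from 0.35 to 1.10 over 13 alternatives, with Atf4 at 237 against 105 CPM, and dissociation and immediate early genes a median of 0.87, with 13 of 16 higher. ER chaperone genes had a median of 0.08, with 18 of 22 between, and -0.21 over members at 100 CPM or more, so no direction is given. Of 9 p53 targets 6 were higher (median 0.68), such as Mdm2, which degrades p53, at 0.68 log2, while Cdkn1a differed by -0.05. Cholesterol genes had a median of -1.55. Cluster 3, which Fdps leads, held 209 cells in G and 6 in GPH, and in cluster 7 alone Fdps was 1.42-fold and Idi1 4.25-fold lower. All 18 mitosis genes were at least 1.5-fold lower (median -1.30), among them Birc5, an inhibitor of apoptosis active in mitosis, at 34.8 against 132 CPM, but the median was 0.04 with 5 clusters at equal weight. Mitotic cluster 6 held 435 of 1916 vimentin-high cells in G and 106 of 1491 in GPH. The MHC class II and antigen-presenting fibroblast lists changed sign between settings, and no direction is given.

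Named genes of vimentin-high cells in GPH against G were, on the higher side, Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796; 6.34-fold, 632 against 99.6 CPM), Mmp19 (5.01-fold), Lcn2 (4.53-fold), the copper carrier Cp (4.50-fold), Hmox1 (4.43-fold), Hk2 (4.38-fold), C3 (4.22-fold), Saa3 (4.15-fold) and the complement protease C1s1 (4.03-fold). The lowest were Idi1 (6.15-fold lower), Hist1h2ap (5.57-fold), Hist1h2ae (5.30-fold), Bloc1s1 (4.54-fold), Pclaf, which binds PCNA (4.26-fold), Fabp5 (4.10-fold), the microtubule regulator Stmn1 (3.81-fold), Birc5 (3.80-fold) and Fdps (3.58-fold). Hes1 and Hmox1 lead cluster 7, which held 1128 of 1491 vimentin-high cells in GPH and 626 of 1916 in G. Within it Hes1 was 4.01-fold, Hk2 2.37-fold, Mmp19 1.96-fold, Hmox1 1.77-fold, Saa3 1.67-fold, C3 1.63-fold and Lcn2 1.56-fold higher. Idi1 was 4.25-fold, Hist1h2ap 3.45-fold, Stmn1 2.05-fold and Fdps 1.42-fold lower there. Birc5 was 1.16-fold higher in that cluster, with a log2 interval from -0.43 to 0.90, so it had no direction there. Hes1, Hk2 and Bloc1s1 followed the split of the library pairs.

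GPH against PH asked what gemcitabine added to the other drugs. In vimentin-high cells all 6 measured genes of each of the interferon, MHC class I and MHC class II lists were at least 1.5-fold higher in GPH, with medians of 1.25, 0.87 and 1.61. All 11 cholesterol genes were lower (median -1.67), and 8 of 9 inflammatory fibroblast genes higher (median 2.04). Autophagy genes had a median of 0.37, with 7 of 19 higher and 2 lower, lysosome genes 0.57, with 9 of 18 higher, ER chaperone genes 0.39, with 5 of 20 higher, and integrated stress response genes 0.39, with 6 of 13 higher. Of 7 p53 targets 5 were higher (median 1.06). Mitosis genes had a median of -0.71, with 11 of 18 lower, but -0.15 within mitotic cluster 6, which held 1464 of 10694 vimentin-high cells in PH and 106 of 1491 in GPH, so no direction is given. Cluster 7 held 472 vimentin-high cells in PH and 1128 in GPH. Within it the inflammatory fibroblast median was 0.92, with 8 of 10 higher, and the cholesterol median -0.48, with 3 of 7 lower. The interferon and MHC class I medians were 0.26 and 0.45 there, with 4 of 13 and 1 of 7 higher, and all 6 MHC class II genes stood between. Lysosome, ER chaperone and integrated stress response genes had medians of 0.29, 0.33 and 0.28 in cluster 7, and autophagy genes -0.06.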

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

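Among the tests below, the one on cell depth was written before its result was seen, with a criterion on single genes added afterwards; the other tests were chosen after the results were seen.

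Y-linked transcripts stood out because their level was highest in the libraries labelled with gemcitabine. In vimentin-high cells they reached 8.43 CPM in G and 11.95 CPM in GPH, against 0.0672 CPM in control (0.0290 to 0.132) and 0.463 CPM in PH (0.353 to 0.596). Free RNA or doublets from keratin-high cells are excluded as the whole source, since the vimentin-high level in GPH was 31.7% of the keratin-high level (lower bound 27.4%), while the leading genes of clusters 22 and 24 stood at a median of 0.847% and at most 2.33%. Tumour cells of another stock or subclone may have formed these tumours, as keratin-high cells of GPH held 37.8 CPM, but origin and treatment cannot be told apart. PH, with a keratin-high share of 0.0358% by cluster, had a Y-linked level above control yet far below G. By own markers 8.41% of PH cells took the ductal tumour type, but that setting types every cell and has no Krt19 threshold. An effect of the drugs on Y-linked genes also stays open and was not tested.

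The split of control and GPH from PH and G was found by looking for genes that follow any pairing of the libraries. A difference between library batches may be its source: the 6 genes, chosen without keratin-high cells, went the same way there, with a median of 1.68 log2 for GPH over G, and the other pairings gave 0 genes by the same rule. Cell depth is argued against, because deep and shallow vimentin-high cells of control differed by a signed median of 0.0167 log2, against 1.25 between the pairs. AY036118 differed by -1.34 log2 with depth, against the direction of the pairs, and none of the 6 genes reached 1/2 of its own difference in that direction. No label names a batch, so this stays a hypothesis, and GPH against control is the contrast with the treated library on the same side as control in this split, though not for Y-linked transcripts.

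The immune-rich G library drew attention because its immune share was 71.4%, against 12.95% in control, or 70.3% against 38.2% with each cell assigned by its own markers. The latter setting leaves no cell without a type, so vimentin-high cells can add to its shares. Removal of barcodes with many mitochondrial UMIs is excluded as the whole source. If none of the removed barcodes of G and all of those of the other libraries were immune, the shares would be 59.02% in G (lower bound 58.2) and at most 45.02% elsewhere, or 58.1% and at most 51.3% by the cells' own markers. Gemcitabine as such was weighed through the other library that had it, where the immune share was 4.60%, below the 12.95% of control. An effect of gemcitabine that the added drugs end and a difference between the tissue pieces therefore could both give this pattern, and with 1 library per group they cannot be told apart.

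Opposite directions between cell classes in G against control drew attention in 5 cases, and the differences between classes were not tested. The ER chaperones and ER-associated degradation list had a median of -0.20 in the macrophage or monocyte-like class and 0.25 in vimentin-high cells. Cholesterol genes stood at 0.84 in macrophages and 0.54 in the T cell-like class, against -0.45 in vimentin-high cells. Mitosis genes stood at -1.26 in the NK cell-like class and 0.62 in vimentin-high cells, the latter 0.083 with 5 clusters at equal weight, and interferon genes at 0.38 and -0.44, the latter 0.14 in cluster 7 alone.

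Signals in cells that no comparison used were also above their level in control. Krt19 reached 1933 CPM in G and 2001 CPM in GPH among the barcodes over the mitochondrial limit, against 62.7 CPM in control. Cluster 19, with no name, held 13.2% of PH and 0.119% of control. Like cluster 5, it met the Vim and Xist limits of vimentin-high cells and missed only the depth limit. Cluster 5 held 9.20% of GPH and 4.25% of control, and cluster 23 held 1.31% of GPH and 0 of 10074 cells in control.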

How the results depend on the processing

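Cluster 7 alone, clusters at equal weight and lists without the pair genes were chosen after the data had been seen; the other settings were fixed beforehand. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Of 271 values of the autophagy, lysosome, ER and integrated stress response medians under other settings, 262 stayed inside the interval of the value as reported, and of 44 immune and keratin-high shares 26 did. For medians that interval spans the spread between member genes, so this count says little about how stable they are. In vimentin-high cells the integrated stress response median of PH against control went from -0.20 to -0.70 and still lay inside. So did the ER median of GPH against G, from 0.08 to -0.21. Assigning each cell by its own markers gave immune shares of 38.2% in control, 35.5% in PH, 70.3% in G and 15.4% in GPH. In place of keratin-high shares it gave shares of the ductal tumour type, at 4.50%, 8.41% and 9.65% in control, PH and G. G had the highest immune share under every setting run. A 10% mitochondrial limit gave immune shares of 12.2% in control, 72.8% in G and 3.68% in GPH and a keratin-high share of 50.7% in GPH. Requiring 1000 UMIs and 500 genes gave immune shares of 11.3% in control, 7.26% in PH and 69.98% in G and a keratin-high share of 11.4% in G, which was 11.5% with doublets kept. Outside keratin-high cells, a smaller denominator, immune shares were 79.8% in G and 8.85% in GPH. The cause was not tested for the other shares.

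In vimentin-high cells, cluster 7 alone gave autophagy medians of 0.10 for PH against control and 0.024 for GPH against control, an interferon median of 0.14 and a DNA replication median of -0.20 (0.31 over all clusters) for G against control. For GPH against G it gave 0.40 for lysosome, 0.057 for DNA replication, -0.57 for MHC class II and -0.46 for antigen-presenting fibroblast genes. With 5 clusters at equal weight, which holds the share of mitotic cells fixed, the mitosis median was 0.23 for GPH against control and 0.038 for GPH against G, where DNA replication stood at 0.28, autophagy at 0.18, lysosome at 0.38, MHC class II at -0.52 and antigen-presenting fibroblast genes at -0.35, the last -0.22 for GPH against control. Cells without a mitosis UMI gave -0.075 for DNA replication in G against control, and -0.24 for MHC class II and -0.12 for antigen-presenting fibroblast genes in GPH against G. There, MHC class II was -0.14 both as the mean of each cell's CPM and after thinning. Thinning gave a lysosome median of 0.54 in cluster 24. Over the whole library, classes at equal weight gave 0.16 for autophagy in PH against control and, for ER genes, 0.10 in G and 0.056 in GPH against control, from 0.41 and 0.47. Apart from the fixed mitotic share, the cause was not tested.

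Of the other list medians 29 moved nearer to 0, 13 moved farther from it and 16 took the other sign, and of the other shares 39 were higher and 10 lower. Named gene ratios were run with scaling by the median of ratios, the mean of each cell's CPM, thinning, the 10% mitochondrial limit and doublets kept. Of these ratios 209 moved nearer to 0, 130 moved farther and 0 changed sign. Cluster 7 alone was not among these settings. There, Birc5 in GPH against G stood at 0.21 log2 (-0.43 to 0.90), from -1.93. Assigning cells by markers gave no value for vimentin-high cells, which no marker list describes.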

Other observations

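No test was run on the values below.

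In the NK cell-like class of G against control, 5 of 10 measured type I interferon genes were at least 1.5-fold higher and none lower, with a median of 0.38. Ifit1, which binds viral RNA, was at 70.8 against 3.86 CPM, and Oasl1, of the oligoadenylate synthetase family, at 28.4 against 3.22. The class held 1081 cells in G and 260 in control.

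In vimentin-high cells of GPH against control, 5 of 6 genes of gemcitabine transport and metabolism stood between 1.5-fold lower and higher (median -0.31), and Samhd1, which degrades nucleotides, was at 138 against 75.8 CPM. Spp1, named in the vitamin D receptor list, was at 4838 against 1424 CPM. In keratin-high cluster 22 of GPH against G, MHC class I genes had a median of 0.55, with 5 of 11 higher and none lower, H2-T23 being at 182 against 57.1 CPM, and Hk2 was at 397 against 149; both genes followed the split of the library pairs in vimentin-high cells. The integrated stress response list had a median of 0.48 there, and the lysosome list 0.39.

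Depth and quality set limits to these data. GPH kept 203 immune cells, of which 51 were macrophage-like and 53 T cell-like, so no gene ratios were given for its immune cells. Cluster 4 was 18.1% of PH and 0.576% of control, so its genes belong mostly to the PH library.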
